A study of Mus musculus with 13 samples.

How the data were processed

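The series holds 13 Affymetrix Mouse Gene 1.0 ST arrays of mouse rectum, grouped from the labels as adenocarcinoma (5 arrays), inflamed mucosa (4) and normal mucosa (4). Replicate numbers are those of the sample titles. The deposited values are log2 RMA expression values per transcript cluster, computed by the authors with Affymetrix Expression Console version 1.1, per the series' design text and the labels. Scans were processed with Affymetrix GeneChip Command Console version 2.0, per the same text, and the submitters' processing notes also name Partek without a role. RMA corrects background, normalises arrays to a common distribution and summarises probes, so differences in total RNA between groups are removed and differences of dim genes are compressed. Per the labels' protocols, prolapses were frozen, a pathologist located tumours on stained sections of 5 µm, and tumour and adjacent mucosa were dissected from sections of 50 to 100 µm, whereas control mucosa was scraped. No scan date or slide was used here, and no background measure per probe.

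The labels give all 13 samples the same floxed Villin-Cre genotype in one field, while another field calls the normal samples controls. Groups were taken from the titles and tissue labels, and normal mucosa is called control as the design text does. Whether arrays of 1 number came from 1 mouse is not stated. The labels give tumour and inflamed samples of 1 number the same sex and age, and deviations from the group means correlated at 0.319, 0.198, 0.199 and 0.387 in the 4 same-numbered pairs, each array best with its own number among tumour and inflamed arrays. Adenocarcinoma 3 correlated more highly, at 0.218, with normal mucosa 4. Tumour and inflamed arrays were therefore taken as paired by number. Correlations of normal arrays with same-numbered others lay between -0.126 and 0.0413 and were not taken as pairs. The main model has no block, as fixed in advance. The fixed replicate block among the alternatives joins all arrays of 1 number, also the normal arrays that were not taken as pairs.

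Of 35556 transcript clusters, 21789 name 1 gene in the platform annotation of 2016, 1621 name several and 12146 are not listed. Symbols were updated through Entrez gene identifiers, of which 21698 matched a RefSeq table of assembly GRCm38.p6. The cluster with the highest mean was kept per gene, giving 19938 genes, 999 of which have more than 1 cluster. Clusters naming several genes or none were left out of the named results. The array's genome build is not given in the sources used here, so no coordinates are printed. No filter on dim genes was applied and no column was left unused.

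Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 fit of the 3 groups, Benjamini-Hochberg adjusted p below 0.05). Lists of genes (15 gene lists and 15 cell type lists, fixed before the data were examined, 541 of 588 symbols measured) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 90 tests, with an estimated correlation and fry as alternatives. Of 57 list calls, 0 held with an estimated correlation. Some lists share genes. Marker scores, the mean log2 value of a list per array, were compared with two-sided exact permutation tests adjusted over 45 tests. These tests treat all arrays as independent, also the tumour and inflamed arrays that were taken as pairs. Genes named in the text come from a rule fixed before the data were examined, with exceptions named where they occur. It took Itga6 and Itgb4, the 10 largest rises and 10 largest falls per comparison among called genes whose arrays do not overlap, up to 4 members with the smallest adjusted p of each list that passed, and the hemidesmosome list. Predicted genes and immunoglobulin, receptor segment and olfactory genes were not named. The text uses part of that set.

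Alternatives were the replicate number as a fixed or random block, sex and age as covariates, the 2 groups alone, a filter on the dimmest genes, other scalings, all clusters, a 2-fold threshold, other variance models, array weights, the smooth muscle score as a covariate and leaving out each array. On simulated data made from the real means and spreads, the test of inflamed against normal mucosa recovered 52.2% of 67 genes changed by 0.5 on the log2 scale, 91.0% of 67 changed by 1 and 98.5% of 66 changed by 2. For adenocarcinoma against normal mucosa the shares were 58.2%, 89.6% and 100%, and for adenocarcinoma against inflamed mucosa 53.7%, 92.5% and 98.5%. Calls among the 19718 unchanged genes numbered 14, 13 and 11.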

Results

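RNA from 13 pieces of mouse rectum was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per piece. These arrays probe each transcript along its length. The pieces were 5 adenocarcinomas and 4 pieces of the inflamed mucosa beside them, both from rectal prolapses of mice lacking α6 integrin in the intestinal epithelium, and 4 pieces of normal rectal mucosa from control mice. α6 integrin (Itga6) pairs with β4 integrin (Itgb4) as the laminin receptor of hemidesmosomes, the junctions that hold epithelial cells to the basement membrane. The design asks what distinguishes inflamed mucosa from normal mucosa, tumour from normal mucosa, and tumour from the inflamed mucosa around it. Tumour and inflamed tissue were dissected from cryosections of prolapses, whereas normal mucosa was scraped, so both comparisons with normal mucosa also compare 2 ways of collecting tissue. Tumour mice were 53, 60, 60, 64 and 80 weeks old, and normal mice 53, 60, 64 and 70 weeks. The number of arrays limits the precision. Array medians lay between 6.41 and 6.59 on the log2 scale, and correlations between arrays between 0.943 and 0.990. The first principal component, with 49.93% of the variance, set the 4 normal arrays apart from the other 9.

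Itga6 (transcript cluster 10472820) was measured at 11.50, 11.52, 11.62, 11.60 and 11.44 in adenocarcinomas 1, 2, 3, 4 and 6, at 11.14, 10.90, 11.10 and 11.20 in inflamed mucosa 1 to 4, and at 10.96, 10.75, 11.16 and 10.76 in normal mucosa 1, 2, 4 and 6. Itga6 was higher in tumour than in normal mucosa by 0.63 ± 0.10 (log2 difference ± SE, n = 5 and 4, limma, adjusted p = 0.000272). The inflamed minus normal difference in Itga6 was 0.18 ± 0.10 and did not pass (n = 4 and 4, adjusted p = 0.195). Against inflamed mucosa, Itga6 was higher in tumour by 0.45 ± 0.10 (adjusted p = 0.0134), a call lost without inflamed mucosa 2 (0.39, adjusted p = 0.0555). Itgb4 (cluster 10382713) was higher in tumour than in normal mucosa by 0.43 ± 0.11 (adjusted p = 0.00762) and than in inflamed mucosa by 0.59 ± 0.11 (adjusted p = 0.00508). Both clusters cover whole genes, the deleted part is not given in the sources used here, and other cells of the tissue also carry these transcripts, so these values do not check the genotype labels. The sex labels were met on all 13 arrays: Xist lay between 10.95 and 12.05 on the 5 female arrays and was at most 5.37 on the 8 male arrays.

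**Figure D1:**
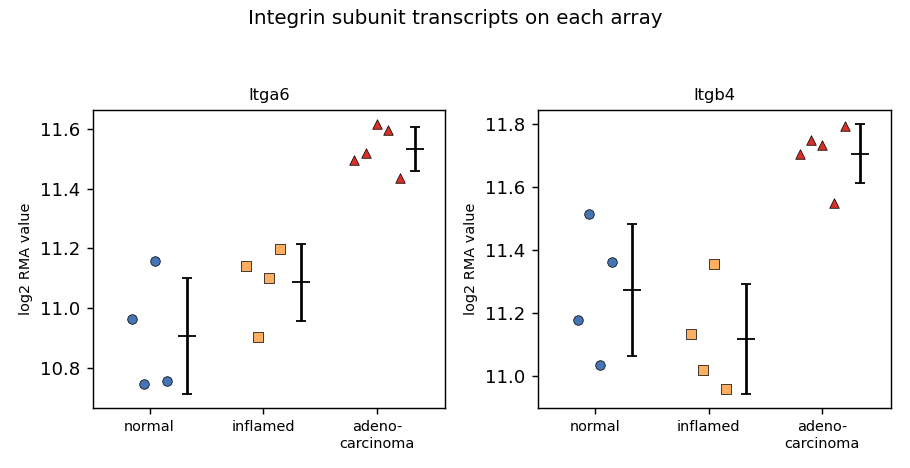
Log2 values of Itga6 and Itgb4 on each array, with 1 point per array by tissue group and the group mean ± SD beside the points. All 5 adenocarcinoma arrays lie above the normal and inflamed arrays for both genes, for Itga6 from 11.44 to 11.62.

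Inflamed mucosa carried far more transcript of contractile, stromal, vascular and macrophage genes than normal mucosa, and less of the genes of mature colonocytes. Among the genes the naming rule admits, the largest rise was in Serpina3n (cluster 10398075), a secreted serine protease inhibitor of the acute phase, at 12.49 ± 0.31 against 7.18 ± 1.79 (mean ± SD, n = 4 and 4, 39.6-fold, adjusted p = 4.03e-05), where normal mucosa 6 stood apart at 9.87. That array was also far above the other normal arrays in Acta2, Fn1, Myh11, Pdgfra and Mmp2. Without it the rises were 73.7-fold for Serpina3n, 43.7-fold for Adck1 and 5.39 on the log2 scale for Acta2. Next came the smooth muscle genes Myl9 (30.1-fold), Cnn1 (27.3-fold), Des (27.2-fold) and Acta2 (25.3-fold), followed by Aspn (23.7-fold), Pgm5 (23.6-fold), the matrix glycoprotein Fn1 (23.1-fold) and Igfbp5 (22.4-fold), each with adjusted p at or below 2.15e-05. The cluster listed as Adck1 rose 25.9-fold (adjusted p = 0.00013), but a second cluster of Adck1 differed by -0.11 on the log2 scale, so the gene behind this signal is uncertain. Transcripts absent by sex (Xist in males, Y-linked genes in females) still read as high as 5.57 on these arrays. The mean of normal mucosa lay no higher for Adck1 (4.71), Aspn (4.56) and, below, Vip (5.35). Normal mucosa as a group is thus not shown to express them, though a single array may lie higher (SD 1.56 for Adck1 and 1.10 for Aspn). The size and order of these folds depend on the background. The largest falls were in Cyp2d12 (3.27 ± 0.29 on the log2 scale, fell 9.62-fold, adjusted p = 5.3e-06), Naaladl1 (8.43-fold), St8sia5 (7.16-fold), Clec2e (7.02-fold), Slc37a2 (6.70-fold) and the transglutaminase Tgm3 (6.45-fold). Further falls were in the deiodinase Dio1 (5.78-fold), Eno3 (4.97-fold), Trpv3 (4.78-fold) and the phosphate transporter Slc34a2 (4.76-fold). Cyp2d12 and Clec2e belong to families of similar genes whose probes can cross-hybridise.

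Among the marker lists, all 13 smooth muscle genes measured rose in inflamed mucosa, 13 adjusted over the list alone, with Myh11 (myosin heavy chain of smooth muscle) up 18.2-fold (camera, adjusted p = 9.63e-17, adjusted p = 0.066 with an estimated correlation). All 13 endothelial markers rose, 13 adjusted over the list alone, among them Pecam1 (6.09-fold) and Cdh5 (6.61-fold), with adjusted p = 5.58e-16 and adjusted p = 0.066 with an estimated correlation. Of 16 fibroblast and collagen genes 14 rose, 14 adjusted over the list alone, such as Col1a2 (3.85-fold) and the growth factor receptor Pdgfra (8.14-fold), with adjusted p = 1.67e-13 and adjusted p = 0.066 with an estimated correlation. Macrophage and dendritic cell markers rose in 11 of 19 genes, 11 adjusted over the list alone, including Mrc1 (6.22-fold) and Lyz2 (6.75-fold), with adjusted p = 1.37e-08 and adjusted p = 0.229 with an estimated correlation. Plasma cell genes Derl3 (6.68-fold), Jchain (12.2-fold, 6.92-fold without normal mucosa 2) and Tnfrsf17 (2.38-fold) were among 10 of 14 B and plasma cell markers that rose, 10 adjusted over the list alone, with adjusted p = 6.73e-06 and adjusted p = 0.165 with an estimated correlation. Enteric nerve markers rose in 8 of 13 genes and none fell, with 9 and 1 adjusted over the list alone, for example the neuropeptide Vip (10.1-fold) and Stmn2 (6.19-fold), with adjusted p = 0.000102 and adjusted p = 0.281 with an estimated correlation. Mast cell markers rose in 6 of 12 genes, 8 adjusted over the list alone, with adjusted p = 0.0011 and adjusted p = 0.339 with an estimated correlation, and the list call ended without the dimmest genes. The mast cell score was high in inflamed mucosa 2 and 4 (7.71 and 7.60), while inflamed mucosa 1 and 3 (6.11 and 6.25) lay near normal mucosa 1 (6.19), and the score test did not pass (two-sided exact permutation p = 0.0571, adjusted p = 0.083). Neutrophil markers did not shift as a list, with 1 of 16 higher and 2 lower over all genes and over the list alone (adjusted p = 0.941).

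Lists of epithelial genes differed as well, and so did matrix protease and inflammasome genes, which other cells also express. The pan-epithelial score was 11.45 ± 0.07 in inflamed and 11.64 ± 0.04 in normal mucosa (SD, two-sided exact permutation p = 0.0286, adjusted p = 0.0495), on arrays whose smooth muscle scores were 10.3 ± 0.4 and 7.2 ± 0.5. Of 28 mature colonocyte genes 18 fell and none rose, 19 falls adjusted over the list alone, with Mep1a, a brush border protease, down 3.86-fold, Ceacam20 2.30-fold and the brush border cadherin Cdhr2 2.16-fold (adjusted p = 1.41e-05, adjusted p = 0.281 with an estimated correlation). Genes of colonocyte lipid and drug metabolism fell in 9 of 28 and rose in 1, with 10 and 1 adjusted over the list alone (adjusted p = 0.00266, adjusted p = 0.447 with an estimated correlation). Proliferation genes rose in 11 of 29, 14 adjusted over the list alone, including Rrm2 (1.87-fold), a subunit of ribonucleotide reductase, and the replication factor Mcm3 (1.86-fold), with adjusted p = 9.25e-08 and adjusted p = 0.356 with an estimated correlation. The proliferation scores overlapped (two-sided exact permutation p = 0.0857), with inflamed mucosa 2 at 7.80 below normal mucosa 4 and 6 (7.95 and 8.15) and normal mucosa 2 lowest at 6.84. Without normal mucosa 2 the list's mean shift was 0.40 in place of 0.68 (adjusted p = 5.56e-06). Stem cell and Wnt target genes rose in 11 of 27 and fell in 2, with 12 and 3 adjusted over the list alone, led by Dkk3 (4.10-fold), a gene also made by stromal cells, and Smoc2 (2.09-fold), with adjusted p = 0.0013 and adjusted p = 0.229 with an estimated correlation. The gelatinase Mmp2 (12.2-fold) and its inhibitor Timp2 (9.51-fold) led the matrix protease list, in which 11 of 22 rose and 1 fell, the same counts adjusted over the list alone (adjusted p = 7.39e-06, adjusted p = 0.161 with an estimated correlation). Goblet cell genes rose in 5 of 17 and fell in 1, the same counts adjusted over the list alone, with Spink4 up 3.22-fold (adjusted p = 0.0124, adjusted p = 0.328 with an estimated correlation). This list call ended with the replicate block (adjusted p = 0.064), without the dimmest genes (adjusted p = 0.102) and with cyclic loess (adjusted p = 0.0672). Inflammasome genes fell in 5 of 19, 5 adjusted over the list alone, among them Gsdmd (1.62-fold lower), the pore former of pyroptosis, and Nlrp6 (1.99-fold lower), with list adjusted p = 0.0257 and adjusted p = 0.337 with an estimated correlation. This list call ended without normal mucosa 1 (adjusted p = 0.0502) and without normal mucosa 6 (adjusted p = 0.0522), and the call of Nlrp6 without both (-0.77, adjusted p = 0.0971).

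In the hemidesmosome list, 8 of 17 genes rose and 1 fell in inflamed mucosa, with 8 and 3 adjusted over the list alone (adjusted p = 0.00274, adjusted p = 0.229 with an estimated correlation). Those that rose included basement membrane genes: Nid1 (10.7-fold), the laminin chains Lamc1 (5.19-fold) and Lamb1 (4.71-fold), the type IV collagen Col4a1 (2.16-fold) and Lama5 (1.59-fold). Lama5 passed only narrowly (limma, adjusted p = 0.0494). The laminin receptor subunit Itga3 fell by 0.49 ± 0.11 on the log2 scale (adjusted p = 0.00584). Itgb4 (-0.15), Plec (-0.02), Col17a1 (-0.58) and Lamb3 (-0.42) did not pass, and Col17a1 passed without normal mucosa 6 (-0.72, adjusted p = 0.0343) and with age as a covariate (-0.63, adjusted p = 0.0409).

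In all, 5322 of 19938 genes differed between inflamed and normal mucosa (limma, adjusted p below 0.05), 2730 higher and 2592 lower, and 1087 of them at least 2-fold (875 higher and 212 lower). The balance of directions moved with the scaling. With arrays centred on their medians 2408 were higher and 3139 lower, and with cyclic loess 2866 and 2014. The median over all genes was -0.09. No gene was called with the smooth muscle score as a covariate (623 at an unadjusted p below 0.05), a score whose inflamed and normal arrays do not overlap, and 3524 were called without inflamed mucosa 2.

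**Figure D2:**
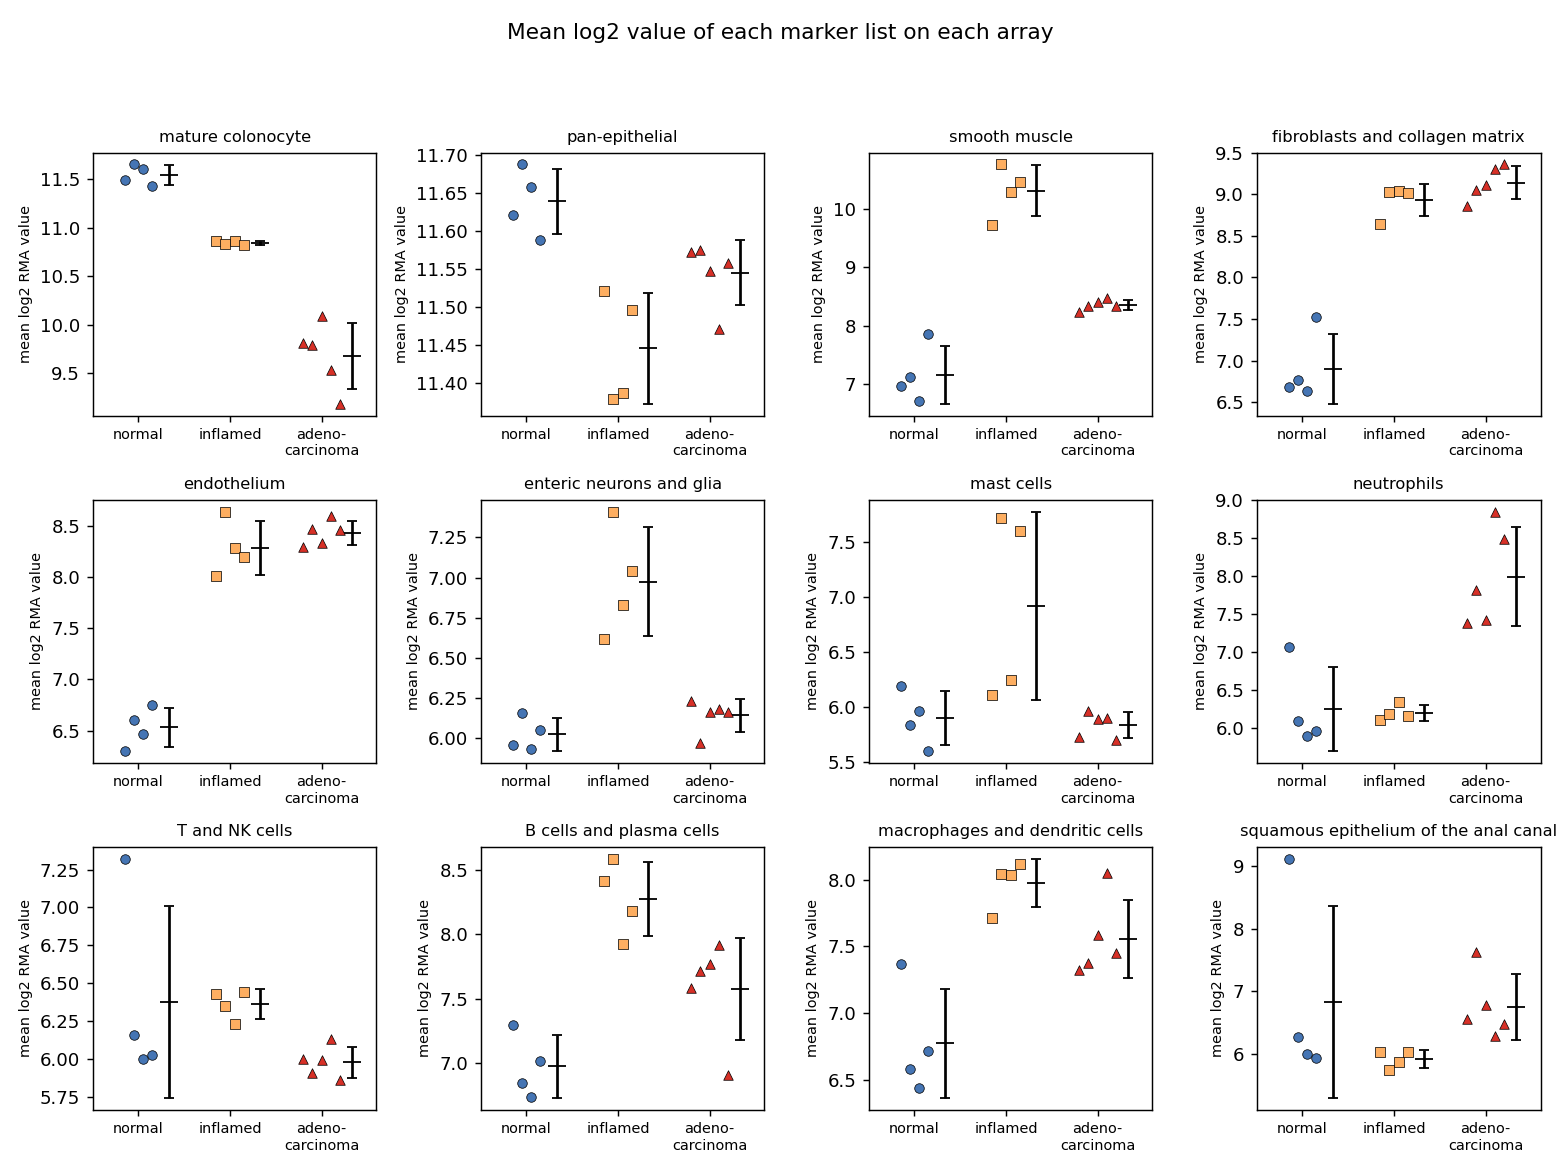
Mean log2 value of each of 12 marker lists on each array, 1 point per array by tissue group, with the group mean ± SD beside the points and an axis range of its own in each panel. Smooth muscle averages 10.3 in inflamed mucosa, 8.36 in adenocarcinoma and 7.16 in normal mucosa, and mature colonocyte genes 10.85, 9.68 and 11.54.

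Adenocarcinomas differed from normal mucosa by more transcript of matrix protease, stromal and neutrophil genes and less of mature colonocyte genes. The collagenase Mmp13 (cluster 10583044) had the largest measured rise, to 11.51 ± 0.48 from 5.52 ± 0.08 (n = 5 and 4, 63.2-fold, adjusted p = 3.68e-08). It was followed by Igfbp5 (42.9-fold), Serpina3n (39.7-fold, and 73.9-fold, above Mmp13, without normal mucosa 6) and the serum amyloid gene Saa3 (30.3-fold). Next came the matrix proteins Tnc (26.4-fold) and Col12a1 (24.2-fold), the stromelysin Mmp10 (24.0-fold), the antimicrobial lectin Reg3g (23.7-fold), ceruloplasmin (Cp, 22.5-fold) and haptoglobin (Hp, 22.0-fold). Carbonic anhydrase Car4 (cluster 10379866) fell most, to 7.19 ± 0.59 from 13.17 ± 0.12 (63.3-fold lower, adjusted p = 5.61e-09). Tgm3 fell 42.0-fold, Cyp2d12 33.3-fold, Saa1 29.4-fold and the water channel Aqp8 29.2-fold. Further falls were in the peptide transporter Slc15a1 (25.9-fold), the chloride exchanger Slc26a3 (24.0-fold, 15.8-fold without adenocarcinoma 6), the sodium-proton exchanger Slc9a3 (23.4-fold), Prss30 (22.9-fold) and Slc37a2 (18.1-fold). All 20 had adjusted p at or below 4.53e-05. The mean of normal mucosa lay no higher than absent transcripts for Mmp13 (5.52), Reg3g (5.49), Cp (5.52) and, below, Reg3b (5.07), Pla2g2a (5.53) and Retnlg (5.48). So did the tumour mean for Cyp2d12 (5.39) and Saa1 (4.98). The size and order of these folds depend on the background. Saa1, Saa3 and the Reg3 genes have close relatives, so their probes may not separate the family members fully.

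Of 28 mature colonocyte genes 27 fell in adenocarcinoma, 27 adjusted over the list alone (camera, adjusted p = 4.83e-14, adjusted p = 0.0714 with an estimated correlation). Colonocyte metabolism genes fell in 16 of 28 and rose in 2, with 18 and 3 adjusted over the list alone, led by the cytochromes Cyp4f14 (13.4-fold lower) and Cyp3a13 (9.87-fold lower), with adjusted p = 0.000146 and adjusted p = 0.339 with an estimated correlation. Matrix proteases and inhibitors rose in 18 of 22 and fell in 1, with 19 and 1 adjusted over the list alone, among them Mmp3 (19.1-fold) and Mmp14 (4.52-fold), with adjusted p = 5.8e-14 and adjusted p = 0.0651 with an estimated correlation. Regeneration and fetal-like genes rose in 13 of 18, 13 adjusted over the list alone, with the prostaglandin synthase Ptgs2 up 17.5-fold and Ccn2, also a stromal gene, 8.79-fold (adjusted p = 7.78e-09, adjusted p = 0.129 with an estimated correlation). Proliferation genes rose in 21 of 29, 26 adjusted over the list alone, Rrm2 by 2.75-fold and Mcm3 by 2.02-fold (adjusted p = 6.09e-09, adjusted p = 0.337 with an estimated correlation). Stem cell and Wnt targets rose in 7 of 27 and fell in 1, the same counts adjusted over the list alone, with the cyclin Ccnd1 up 3.42-fold and the Wnt inhibitor Wif1 3.12-fold (adjusted p = 0.00475, adjusted p = 0.281 with an estimated correlation).

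Of the lists of immune cells and defence, those of neutrophils, macrophages and antimicrobial genes passed upwards in the tumours and that of interferon response downwards. Cytokines, inflammasome genes, T and NK cells, B and plasma cells and mast cells did not pass (adjusted p = 0.181, 0.231, 0.0761, 0.088 and 0.857). Among the normal arrays, normal mucosa 1 stood apart in the neutrophil score (7.07, next 6.09) and in the antimicrobial score (8.74, next 7.75). Neutrophil markers rose in 13 of 16, 13 adjusted over the list alone, with Retnlg up 18.1-fold, S100a9, a subunit of calprotectin, 7.83-fold and the gelatinase Mmp9 4.15-fold (adjusted p = 1.96e-06, adjusted p = 0.245 with an estimated correlation). Macrophage markers rose in 12 of 19 and fell in 1, the same counts adjusted over the list alone (adjusted p = 4.59e-05, adjusted p = 0.356 with an estimated correlation). Antimicrobial genes rose in 11 of 25 and fell in 5, with 11 and 6 adjusted over the list alone, Reg3b by 19.0-fold and the phospholipase Pla2g2a by 13.1-fold (adjusted p = 0.0378, adjusted p = 0.356 with an estimated correlation). This list call ended with the replicate block (adjusted p = 0.0882) and without normal mucosa 2, 4 or 6 (adjusted p = 0.0714, 0.0577 and 0.058). Interferon response and antigen presentation genes fell in 15 of 25 and none rose, 16 falls adjusted over the list alone (adjusted p = 0.000145, adjusted p = 0.527 with an estimated correlation). Ifit1 was 12.2-fold lower, the transcription factors Irf7 and Irf1 7.09-fold and 2.48-fold lower, and B2m, the light chain of class I molecules, 1.79-fold lower. The scores of this list on the female normal arrays 1 and 6 were 10.83 and 9.64, and on the male normal arrays 2 and 4 they were 8.49 and 8.68, with adenocarcinoma 4 between them at 8.62. Without normal mucosa 1 the list's mean shift was -0.82 in place of -1.29 (adjusted p = 0.00187). A second cluster of Irf1 differed by -0.44 on the log2 scale.

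Stromal markers were higher in tumour than in normal mucosa too. All 13 endothelial markers rose, 13 adjusted over the list alone, Cdh5 by 10.3-fold and Pecam1 by 6.27-fold (adjusted p = 2.96e-15, adjusted p = 0.066 with an estimated correlation). Fibroblast genes rose in 14 of 16, 14 adjusted over the list alone, with Col1a1 up 7.30-fold and Col1a2 6.94-fold (adjusted p = 1.67e-13, adjusted p = 0.066 with an estimated correlation). Smooth muscle genes rose in 8 of 13 and fell in 1, with 9 and 1 adjusted over the list alone, Acta2 by 11.3-fold, or 18.9-fold without normal mucosa 6 (list adjusted p = 9.87e-05, adjusted p = 0.337 with an estimated correlation). The list of regulators of epithelial-mesenchymal transition, which holds many stromal genes, rose in 13 of 20 and fell in 1, with 14 and 2 adjusted over the list alone, and the tight junction gene Ocln fell 2.07-fold (adjusted p = 2.14e-06, adjusted p = 0.0651 with an estimated correlation). In the hemidesmosome list 10 of 17 rose and none fell, 11 rises adjusted over the list alone (adjusted p = 9.25e-08, adjusted p = 0.0651 with an estimated correlation). Among them were the plakin Plec (1.35-fold) and basement membrane genes: Lamc1 (7.02-fold), Lamb1 (6.17-fold), Col4a1 (3.75-fold) and Lama5 (3.26-fold). Col17a1 (-0.09), Dst (-0.24), Cd151 (-0.20), Lama3 (0.18), Lamb3 (0.39), Itga3 (0.16) and Bcam (0.36) did not pass (log2 differences). The call of Plec (adjusted p = 0.0225) was lost without adenocarcinoma 2 (0.37, adjusted p = 0.058), without normal mucosa 4 (0.33, adjusted p = 0.0682) and with cyclic loess (0.39, adjusted p = 0.0541).

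In all, 7133 of 19938 genes differed between adenocarcinoma and normal mucosa, 3266 higher and 3867 lower, 1389 of them at least 2-fold (864 higher and 525 lower). More genes were higher than lower with cyclic loess (3276 and 3091) and without the dimmest genes (3189 and 2760). More were lower with arrays centred on their medians (3087 and 3787). The median over all genes was -0.10. With the smooth muscle score as a covariate, a score whose tumour and normal arrays do not overlap, 1233 genes were called.

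**Figure D3:**
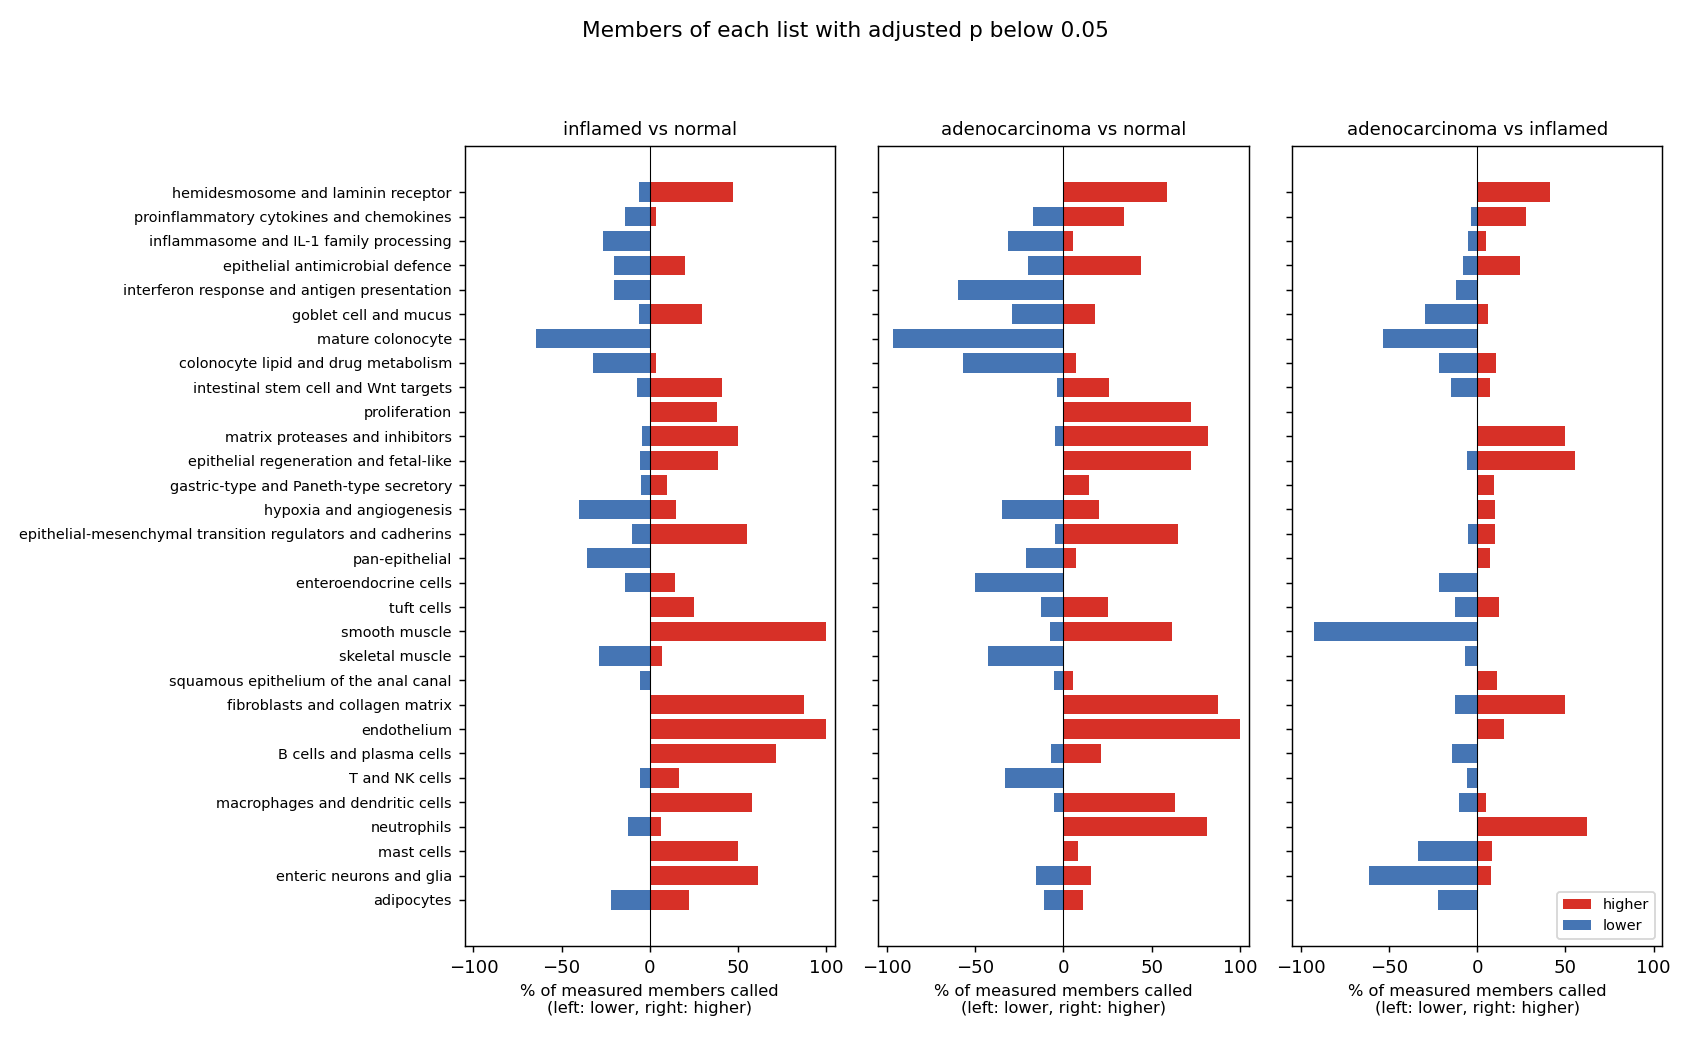
Share of the measured members of each of 30 lists called higher (bars to the right) or lower (bars to the left) at adjusted p below 0.05 in each comparison, in percent. In inflamed mucosa 13 of 13 smooth muscle genes were higher than in normal mucosa, and in adenocarcinoma 12 of 13 were lower than in inflamed mucosa.

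Adenocarcinoma and the inflamed mucosa beside it were collected in the same way. Here too the tumours had more transcript of matrix protease and neutrophil genes and less of mature colonocyte genes, and they had less of smooth muscle genes. The smooth muscle score was 8.36 ± 0.09 in tumour and 10.31 ± 0.44 in inflamed mucosa (mean ± SD, n = 5 and 4). Differences between these groups may therefore also follow the tissue layers that each piece held, which was not tested. Mmp13 was 11.51 ± 0.48 against 6.65 ± 0.85 (n = 5 and 4, 29.0-fold higher, adjusted p = 2.72e-06). Saa3 (20.1-fold), Reg3g (19.5-fold), Reg3b (19.2-fold) and Mmp10 (17.0-fold) followed. Next were the cytokine Il1a (12.8-fold), the arginase Arg1 (12.7-fold), Itgb8, an integrin subunit that binds latent TGF-β (12.3-fold, cluster 10403229), S100a9 (10.2-fold) and the chemokine Cxcl2 (9.54-fold). Each had adjusted p at or below 0.0042. Slc9a3 fell most, to 5.71 ± 0.53 from 10.66 ± 0.25 (31.0-fold lower, adjusted p = 7.5e-08), ahead of Car4 (29.3-fold), Slc26a3 (-3.59 on the log2 scale, -2.99 without adenocarcinoma 6), Vip (9.66-fold), desmin (Des, 9.50-fold), Sectm1b (9.14-fold), the muscarinic receptor Chrm2 (9.07-fold), Pgm5 (8.56-fold), Aqp8 (8.35-fold) and Slc15a1 (8.30-fold). The mean of inflamed mucosa lay no higher than absent transcripts for Reg3b (5.06), Il1a (4.50), Cxcl2 (4.98) and, below, Mmp8 (4.67), Cxcl5 (5.20) and Sprr2h (5.22). So did the tumour mean for Vip (5.42) and, below, Chrna3 (5.09) and Cd163 (5.42). The size and order of these folds again depend on the background.

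Smooth muscle genes fell in 12 of 13, 13 adjusted over the list alone, with Myh11 6.52-fold lower (camera, adjusted p = 1.87e-20, adjusted p = 0.0651 with an estimated correlation). Enteric nerve markers fell in 8 of 13, 8 adjusted over the list alone, the receptor Chrna3 by 3.98-fold, and 1 rose, the tyrosine kinase Ret (1.99-fold), with adjusted p = 4.67e-07 and adjusted p = 0.173 with an estimated correlation. Mast cell markers fell in 4 of 12 and rose in 1, with 9 and 1 adjusted over the list alone, Kit by 2.00-fold (adjusted p = 3.7e-05, adjusted p = 0.256 with an estimated correlation), and the list call ended without the dimmest genes. The high scores of inflamed mucosa 2 and 4 (7.71 and 7.60) carry most of this fall, while inflamed mucosa 1 and 3 (6.11 and 6.25) lay close to the tumours (5.70 to 5.96). Kit varied little among inflamed arrays (SD 0.20), unlike Cpa3 of the same list (SD 2.07). Cpa3 differed by -2.53 on the log2 scale and lay at 5.04 in tumour, no higher than transcripts absent by sex. Of 26 alternatives 14 ended its call with the sign kept, and 1 more, the smooth muscle covariate, reversed its sign without a call. B and plasma cell markers fell in 2 of 14, 12 adjusted over the list alone, the plasma cell receptor Tnfrsf17 by 1.85-fold (adjusted p = 2.75e-06, adjusted p = 0.161 with an estimated correlation). T and NK cell markers fell in 1 of 18, 1 adjusted over the list alone, the costimulatory receptor Cd28 at 2.23-fold lower (adjusted p = 0.00421, adjusted p = 0.543 with an estimated correlation). Macrophage markers fell in 2 of 19 and rose in 1, with 8 and 1 adjusted over the list alone: Cd163 was 2.22-fold lower and Cd14, part of the receptor for lipopolysaccharide, 1.81-fold higher (adjusted p = 0.000808, adjusted p = 0.447 with an estimated correlation). Neutrophil markers rose in 10 of 16, 14 adjusted over the list alone, with the collagenase Mmp8 up 9.19-fold and Retnlg 4.97-fold (adjusted p = 2.96e-15, adjusted p = 0.066 with an estimated correlation). Fibroblast genes rose in 8 of 16 and fell in 2, the same counts adjusted over the list alone: the collagen Col1a1 was 2.96-fold higher and Mfap5, a microfibril protein, 2.89-fold lower (adjusted p = 0.000325, adjusted p = 0.337 with an estimated correlation). Without inflamed mucosa 1 this list's mean shift was 0.14 in place of 0.24 (adjusted p = 0.00933).

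Among epithelial lists, mature colonocyte genes fell in 15 of 28, 19 adjusted over the list alone (adjusted p = 1.12e-16, adjusted p = 0.066 with an estimated correlation). Goblet cell genes fell in 5 of 17 and rose in 1, with 7 and 1 adjusted over the list alone, among them the secretory lineage factor Atoh1 (2.25-fold lower) and the mucin Muc4 (2.01-fold lower), with adjusted p = 0.000152 and adjusted p = 0.161 with an estimated correlation. Enteroendocrine markers fell in 3 of 14, 6 adjusted over the list alone, with the hormone gene Gcg 2.25-fold lower (adjusted p = 0.00209, adjusted p = 0.229 with an estimated correlation). Regeneration and fetal-like genes rose in 10 of 18 and fell in 1, with 13 and 1 adjusted over the list alone, Ptgs2 by 4.47-fold, the epidermal gene Sprr2h by 2.91-fold and the keratin Krt7 by 1.73-fold (adjusted p = 6.92e-12, adjusted p = 0.066 with an estimated correlation). Muc1, a membrane mucin, rose 3.71-fold in the gastric and Paneth-type list, where 2 of 21 rose, 4 adjusted over the list alone (adjusted p = 0.000734, adjusted p = 0.173 with an estimated correlation).

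Matrix proteases rose in 11 of 22, 15 adjusted over the list alone, Mmp3 by 8.23-fold and Mmp9, also a neutrophil marker, by 3.50-fold (adjusted p = 1.42e-13, adjusted p = 0.0651 with an estimated correlation). Cytokine genes rose in 8 of 29 and fell in 1, with 12 and 2 adjusted over the list alone: Cxcl5, a neutrophil chemoattractant, was 7.52-fold and Il11 3.50-fold higher, and the chemokine Ccl8 3.63-fold lower (adjusted p = 0.00021, adjusted p = 0.441 with an estimated correlation). Interferon response genes fell in 3 of 25, 3 adjusted over the list alone, Irf7 by 3.06-fold and B2m by 1.55-fold (adjusted p = 1.9e-05, adjusted p = 0.452 with an estimated correlation). In the hemidesmosome list 7 of 17 rose and none fell, with 11 and 1 adjusted over the list alone (adjusted p = 9.23e-08, adjusted p = 0.0651 with an estimated correlation). Besides Itga6 and Itgb4 these included Itga3 (1.57-fold), the laminin chains Lamb3 (1.75-fold) and Lama5 (2.05-fold) and Col4a1 (1.74-fold). Proliferation genes gave no call in either direction among 29, over all genes or over the list alone, with a median of 0.14 (adjusted p = 0.0894). This list passed upwards without adenocarcinoma 1, inflamed mucosa 3, inflamed mucosa 4 or normal mucosa 2 (adjusted p = 0.0408, 0.0398, 0.0174 and 0.0483).

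In all, 1420 genes differed between adenocarcinoma and inflamed mucosa, 581 higher and 839 lower, 409 of them at least 2-fold. With tumour and inflamed arrays of 1 number as a random replicate block the count was 2279, and all 1420 genes were among them. Without inflamed mucosa 2 it was 775, without inflamed mucosa 4 it was 857, and with the smooth muscle score as a covariate it was 7, among them Itgb8, Slc9a3 and Car4.

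Changes against normal mucosa overlapped between the 2 kinds of prolapse tissue. Both kinds were dissected while normal mucosa was scraped, and tumour and inflamed arrays of 1 number were taken as paired. None of the values below takes out this shared collection or pairing, so the overlap cannot be credited to disease alone. Genes higher in both numbered 2034 and genes lower in both 2030, and 8 were called in opposite directions. Independent lists of these sizes would share 447.2 and 502.7 genes. Across genes, which are not independent replicates, the log2 differences correlated at 0.81, against 0.52 for simulated unchanged groups set against the same normal arrays (mean of 50 sets), and their covariance was 0.271 against 0.0136. When each comparison used its own 2 of the 4 normal arrays, the 6 possible splits gave 1063 to 1389 genes higher in both, 653 to 979 lower in both, 6 to 51 in opposite directions, and a mean correlation of 0.69.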

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

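The tests of the 3 patterns weighed here were chosen after the values had been seen, except the splits of the arrays, which were planned. Of 90 list scores per group 10 had an array far from its group, and of 275 gene values per group 22 did, where chance gives about 1 in 20.

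Normal mucosa 1 lay far above the other 3 normal arrays in 5 list scores: squamous epithelium 9.11 (next 6.28), T and NK cells 7.32 (next 6.16), neutrophils 7.07 (next 6.09), cytokines 6.91 (next 5.93) and antimicrobial defence 8.74 (next 7.75). Of 18 squamous markers, 16 were highest in normal mucosa 1 among the normal arrays, a count that is not independent because the mean of the same markers singled the array out, so squamous epithelium of the anal canal in that scraping stays open. The abundant keratins, chosen after their values were seen, were Krt5 at 12.10, Krt14 at 11.60 and Krt4 at 11.22, against at most 6.52, 7.34 and 5.50 on the other normal arrays, while Krt5 (11.17 and 10.70) and Krt14 (10.63 and 9.88) were also high in adenocarcinoma 2 and 3. A mislabelled tumour or inflamed array is argued against by the mature colonocyte score of normal mucosa 1, 11.49, above all tumour (9.19 to 10.09) and inflamed arrays (10.82 to 10.87). What raised the immune markers stays open, including a difference of that animal, which was not tested.

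Interferon-stimulated genes were lower in adenocarcinoma than in normal mucosa. In a list of 34 measured genes written after some of their values had been seen, 6 of them also in the interferon response list, 31 fell, with a mean of 7.40 ± 0.33 against 9.42 ± 1.09 (SD, n = 5 and 4, two-sided exact permutation p = 0.00794). Normal mucosa 1 as the sole cause is argued against by a difference of -1.61 without it, with every tumour below the other normal arrays. Unequal sexes as the sole cause are argued against by -0.97 within males and -3.14 within females, neither with overlap, though with few arrays of each sex. A smaller epithelial share as the sole cause would lower the pan-epithelial score as far, and it differed by only -0.094. Between inflamed and normal mucosa that score differed by only -0.19, while the smooth muscle score rose by 3.15. It may follow the epithelial share only weakly, so a smaller share is not settled. A difference of the tumour tissue itself, or of the housing or genotype of the control mice, stays open and was not tested, and tumours were lower than inflamed mucosa, collected alike, in 4 of 4 same-numbered pairs.

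Smooth muscle, fibroblast and endothelial markers were higher in prolapse tissue than in scraped normal mucosa. The smooth muscle score minus the fibroblast score was lower in tumour than in inflamed mucosa by a difference of -2.16 without overlap (-1.03 to -0.63 against 1.08 to 1.73). This argues against the same mixture of deeper tissue layers taken along in both dissected groups. It cannot address different amounts of such layers in tumour and inflamed pieces, which stay open and were not tested. The two-sided exact permutation p = 0.00794 treats the arrays as independent and leaves out their pairing by number. Scraping against dissection cannot be told apart from disease, because each group was collected in 1 way: scraped arrays that reached the lowest dissected array in any of the 3 scores numbered 0. A gain of stroma in the disease may contribute and was not tested.

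In each of the 3 comparisons no other split examined called as many genes as the real one, which argues against chance as the source of the counts. The splits are few, so chance is not excluded. The 1 split counted as large in each comparison below is the real one itself. The real split of inflamed and normal arrays called 5322 genes, the highest of the other splits 1 gene, and 1 of 35 splits was as large. For adenocarcinoma and normal mucosa the real split called 7133 genes, the highest other 5329, and 1 of 100 splits drawn was as large. For adenocarcinoma and inflamed mucosa the real split called 1420 genes and the highest other 593, with 1 of 100 as large. Among the 14 of these 100 splits that part as many pairs as the real one, the highest other called 0 genes, while splits that part fewer pairs reached 593. The 14 include the real split. A share of 1 in 14 is not below 0.05, so these splits alone cannot exclude chance.

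Normal mucosa 6 lay far above the other normal arrays in the fibroblast score (7.52, next 6.76) and in Serpina3n at 9.87, Acta2 at 10.03, Fn1 at 9.02, Myh11 at 7.93, Pdgfra at 7.76, Mmp2 at 8.33 and Tnc at 6.86. Other arrays far from their normal group were normal mucosa 4 in Clec2e (10.66) and normal mucosa 2 in Rrm2 (6.62). Among inflamed arrays, array 2 stood apart in the proliferation score (7.80), Dkk3 (8.67) and Gsdmd (8.08), array 1 in the fibroblast score (8.64), Mrc1 (8.31) and Dsg3 (5.29), array 3 in St8sia5 (7.08), Cdhr2 (10.83) and Col1a1 (9.50), and array 4 in Saa3 (7.28), Lama5 (7.41) and Irf7 (11.49). Among tumours, adenocarcinoma 4 stood apart in the pan-epithelial score (11.47), Wif1 (8.76) and Cd14 (10.46), and adenocarcinoma 2 in the enteric nerve score (5.97) and Ret (8.28).

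Among the 12146 clusters with no listed gene, which the comparisons do not use, 273 differed between inflamed and normal mucosa, 842 between adenocarcinoma and normal mucosa and 11 between adenocarcinoma and inflamed mucosa (limma, adjusted p below 0.05).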

How the results depend on the processing

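Of the alternatives, 2 were added after the data were seen: leaving out normal mucosa 1 and 6 together, and fitting the 4 tumour and inflamed pairs alone. Genes changed in inflamed against normal mucosa (5322) stayed within 1.5 times except at 2-fold (1087), with the smooth muscle score as a covariate (0, with 623 at an unadjusted p below 0.05) and without inflamed mucosa 2 (3524). Those in adenocarcinoma against normal mucosa (7133) did so except at 2-fold (1389) and with that covariate (1233). In adenocarcinoma against inflamed mucosa (1420) the exceptions were 2-fold (409), that covariate (7), no moderation of the variance (875), array weights (2296), the random replicate block (2279), and leaving out inflamed mucosa 2 (775) or 4 (857). Leaving out 1 array gave 3524 to 5786, 5344 to 7645 and 775 to 1652 genes. No gene called both with and without a change of setting changed direction (not compared for all clusters). With the number as a fixed replicate block the counts were 4754, 6563 and 1183, and with the 4 pairs alone 1907. The fixed block also ties normal arrays to same-numbered tumour and inflamed arrays, which were not taken as pairs. Calls it ended are therefore not a check of the tumour and inflamed pairs alone. Without normal mucosa 1 and 6 they were 4826, 6178 and 1679. The smooth muscle score separates all 3 groups without overlap, so that covariate takes up group differences by construction in every comparison. The causes of the other changes were not tested.

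List calls numbered 57, 54 with fry, 56 to 60 without 1 array, and 0 with an estimated correlation (23 at an unadjusted p below 0.05, lowest adjusted p 0.0651). The fixed block ended the calls of goblet cell genes in inflamed mucosa, antimicrobial genes in tumour against normal mucosa and endothelium in tumour against inflamed mucosa, and no other list call. Without the dimmest genes 53 lists were called, 50 of them among the 57. The 7 lost were goblet cells, regeneration, squamous markers and mast cells in inflamed against normal mucosa, antimicrobial defence and skeletal muscle in adenocarcinoma against normal mucosa, and mast cells in adenocarcinoma against inflamed mucosa. Cyclic loess gave 56 calls, 54 of them shared, and lost goblet cells, antimicrobial defence and skeletal muscle in the same comparisons. Fry also ended the calls of cytokines, interferon response, T and NK cells, macrophages, squamous markers and endothelium in adenocarcinoma against inflamed mucosa, and of squamous markers in inflamed against normal mucosa. Called marker scores numbered 26 of 45, 9 with medians of the markers, and 0 to 28 without 1 array. They were 0 without any 1 inflamed array or normal mucosa 2, 4 or 6, with 24 to 27 at an unadjusted exact p below 0.05. The smallest exact p is 0.0286 for 4 against 4 or 3 arrays, and rises from 0.00794 to 0.0179 when 5 against 4 become 5 against 3. A test at 0.0286 passes adjustment over 45 tests only when at least 26 reach it, and 20 to 24 did in these settings against 26 in the full data, so the number of arrays limits these calls by construction. Genes changed in both comparisons with normal mucosa numbered 4064, 745 at 2-fold and 2007.3 on average with separate normal arrays, where fewer arrays enter.

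Alternatives were not run for some named members of the hemidesmosome list. Among these were Col4a1 and Lama5 in inflamed against normal mucosa and Col4a1 in adenocarcinoma against inflamed mucosa. Of the other named genes, those that had passed changed direction only with the smooth muscle covariate and no other setting, none with a call. Those that changed direction in inflamed against normal mucosa were Serpina3n (-1.31), Myl9 (-0.32), Adck1 (-0.0399), Acta2 (-1.21), Aspn (-1.32), Tnfrsf17 (-0.19), Mmp2 (-0.0272), Timp2 (-0.48), Stmn2 (-0.85) and Smoc2 (-0.26), and in adenocarcinoma against inflamed mucosa Tnfrsf17 (0.0031), Cpa3 (0.18) and Mcpt4 (0.22). Of named genes that had not passed in inflamed against normal mucosa, Col17a1 changed sign with that covariate (0.54) and Plec with it, sex, array weights and several left-out arrays, none with a call. The fixed block ended the calls of Ms4a1, Cpa3 and Dsg3 in adenocarcinoma against inflamed mucosa and of no other named gene for which alternatives were run. Signal over background was not used here, and some group means of named genes lie no higher than transcripts absent by sex, so dim genes are open to error that replicates do not show.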

Other observations

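Among lists not described above, endothelial markers rose in 2 of 13 genes in adenocarcinoma against inflamed mucosa, with 5 higher and 1 lower adjusted over the list alone (adjusted p = 0.0209, adjusted p = 0.527 with an estimated correlation). That call ended without adenocarcinoma 4 (adjusted p = 0.084) and without inflamed mucosa 1 (adjusted p = 0.224), and without inflamed mucosa 2 the mean shift was 0.30 in place of 0.18 (adjusted p = 8.32e-05). Squamous markers rose in 2 of 18 there, 4 adjusted over the list alone (adjusted p = 0.00142, adjusted p = 0.54 with an estimated correlation). Adenocarcinoma 2 had the highest score of this list, 7.63 against 6.29 to 6.78 in the other tumours. Krt5, chosen after its values were seen, was 11.17 and 10.70 in adenocarcinoma 2 and 3 and 5.98 to 7.38 in 1, 4 and 6. The called genes included Dsg3, a desmosomal cadherin of squamous epithelium (7.41-fold from 4.90, no higher than transcripts absent by sex, adjusted p = 0.0398), whose call ended without any 1 of the 9 adenocarcinoma and inflamed arrays (adjusted p 0.0574 to 0.104). Krt14 differed by 2.53 on the log2 scale and did not pass (adjusted p = 0.0744), nor with the fixed replicate block (0.0645). It passed with the random replicate block (0.0261), with the 4 pairs alone (0.00766), with the 2 groups alone (0.00437), with age (0.0316), with array weights (0.0114) and without normal mucosa 1 (0.00117) or both 1 and 6 (0.00194). Antimicrobial genes rose in 6 of 25 and fell in 2 there, the same counts adjusted over the list alone (adjusted p = 0.00564, adjusted p = 0.269 with an estimated correlation). Colonocyte metabolism genes fell in 6 of 28 and rose in 3, with 11 and 3 adjusted over the list alone (adjusted p = 0.000365, adjusted p = 0.356 with an estimated correlation). Without adenocarcinoma 6 this list's mean shift was -0.18 in place of -0.28 (adjusted p = 0.00317). Hypoxia genes rose in 2 of 20, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.0141, adjusted p = 0.298 with an estimated correlation), and pan-epithelial markers in 1 of 14, with 2 higher and 1 lower adjusted over the list alone (adjusted p = 0.00975, adjusted p = 0.229 with an estimated correlation). Stem cell and Wnt targets (adjusted p = 0.9), inflammasome genes (0.227), epithelial-mesenchymal transition regulators (0.252), tuft cells (0.456), skeletal muscle (0.699) and adipocytes (0.0798) did not pass in that comparison. Adipocyte markers passed downwards without adenocarcinoma 1 (0.0254) or inflamed mucosa 2 (0.0235) and without the dimmest genes (0.047).

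In inflamed against normal mucosa, epithelial-mesenchymal transition regulators rose in 11 of 20 and fell in 2, the same counts adjusted over the list alone (adjusted p = 2.2e-05, adjusted p = 0.066 with an estimated correlation), and regeneration genes rose in 7 of 18 and fell in 1, the same counts adjusted over the list alone (adjusted p = 0.0106, adjusted p = 0.447 with an estimated correlation), a call that ended without the dimmest genes. The squamous list passed downwards with 1 of 18 called over all genes and 0 adjusted over the list alone (adjusted p = 0.0431, adjusted p = 0.705 with an estimated correlation). Without normal mucosa 1 it did not pass (adjusted p = 0.38), nor without adenocarcinoma 1 or 6 (0.0546 and 0.0515) or inflamed mucosa 2 or 3 (0.0573 and 0.0815). Lists that did not pass there were cytokines (adjusted p = 0.238), antimicrobial defence (0.726), interferon response (0.0894), gastric and Paneth-type genes (0.231), hypoxia (0.308), pan-epithelial (0.0604), enteroendocrine (0.618), tuft (0.361), skeletal muscle (0.0639), T and NK cells (0.9) and adipocytes (0.975). Of these, interferon response passed downwards without inflamed mucosa 4, normal mucosa 2 or normal mucosa 4 (adjusted p = 0.028, 0.00123 and 0.0109), without the dimmest genes (0.0271) and with cyclic loess (0.0205). So did pan-epithelial markers without inflamed mucosa 1, inflamed mucosa 4 or normal mucosa 2 (0.0394, 0.0396 and 0.035), with fry (0.00103), without the dimmest genes (0.0263) and with cyclic loess (0.00384), and their score was called lower in inflamed mucosa. Skeletal muscle passed downwards without normal mucosa 4 (0.0272) and with fry (0.043).

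In adenocarcinoma against normal mucosa, skeletal muscle genes fell in 6 of 14, 7 adjusted over the list alone (adjusted p = 0.0268, adjusted p = 0.527 with an estimated correlation), a call that ended without normal mucosa 2 (adjusted p = 0.0719). Lists that did not pass in that comparison were cytokines (adjusted p = 0.181), inflammasome genes (0.231), goblet cells (0.806), gastric and Paneth-type genes (0.461), hypoxia (0.712), pan-epithelial (0.719), enteroendocrine (0.181), tuft (0.947), squamous (0.962), B and plasma cells (0.088), T and NK cells (0.0761), mast cells (0.857), enteric nerves (0.975) and adipocytes (0.361). Without normal mucosa 1, squamous markers (adjusted p = 0.0207), cytokines (0.0479) and B and plasma cells (0.0351) passed upwards. Cytokines also passed without adenocarcinoma 3 (0.0316), B and plasma cells without adenocarcinoma 6 (0.00757), and T and NK cells passed downwards without normal mucosa 2, 4 or 6 (0.0299, 0.0181 and 0.029). With fry, inflammasome genes (0.00995) and enteroendocrine markers (0.0157) passed downwards.

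Median, mean and test direction differed in sign in 11 list tests, none of which passed. In inflamed against normal mucosa these were antimicrobial defence (median -0.20, mean 0.25, test up), gastric and Paneth-type genes (-0.20, 0.03, down), enteroendocrine (-0.02, 0.12, up), neutrophils (-0.05, -0.05, up) and adipocytes (-0.19, 0.17, down). In adenocarcinoma against normal mucosa they were gastric and Paneth-type genes (-0.06, 0.37, up), tuft cells (-0.15, 0.16, up), squamous markers (-0.33, -0.08, up), mast cells (-0.16, -0.06, up) and enteric nerves (-0.20, 0.12, down). In adenocarcinoma against inflamed mucosa they were stem cell and Wnt targets (-0.05, 0.05, up).

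The difference between the sexes in the effect of the tissue was called for 1 gene in inflamed against normal mucosa, 1 in adenocarcinoma against normal mucosa and 0 in adenocarcinoma against inflamed mucosa (limma, 1062, 1931 and 396 genes at an unadjusted p below 0.05), and for 0 of the genes named by the rule. The gene was Mx1 in both cases, an interferon-induced antiviral gene chosen after its values were seen. Inflamed mucosa differed from normal mucosa in Mx1 by -3.13 in females and 0.49 in males, where normal mucosa had 2 arrays of each sex and inflamed mucosa 1 female array. Adenocarcinoma differed by -3.51 in females and -0.37 in males (limma, adjusted p = 0.0271). The male normal arrays lay at 5.45 and 5.34, no higher than transcripts absent by sex (up to 5.57). Males could therefore hardly show a fall in Mx1, and the difference between the sexes may reflect that floor.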
